A study of Mus musculus with 2 samples.

How the data were processed

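Total RNA of Menin WT and Menin KO CD4 T cells, 1 sample each, was measured on 2 one-colour arrays. Per the labels' protocols, naive CD4 T cells were isolated from spleen with a T cell isolation kit and stimulated for 2 days with plate-bound antibody to the T cell receptor beta chain at 3 µg/ml and antibody to CD28 at 1 µg/ml, with IL-2 at 2.5 ng/ml. They were kept in IL-2 for 3 further days. RNA was extracted with TRIZOL, and 500 ng was amplified and labelled with Cy3 by an Agilent Quick Amp kit. The groups were taken from the genotype in the labels.

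Per the file headers, the arrays were Agilent mouse arrays on 1 slide, read in the same scan with Feature Extraction 10.7.3.1 (10.7 in the submitters' processing notes), and the probe annotation was on mm9. The intensity used here is the processed signal the authors deposited for each spot, which per the file headers is background-subtracted, detrended and on a linear scale, with dim spots set to a surrogate value and no scaling between arrays. The authors' value table holds log2 values. Set against the scanner signals, each column was log2 of the processed signal minus a constant per array, for 99.7% of probes within 0.01 on either array, so its scale, centring and direction are known. Its column medians were -3.97 for WT and -3.90 for KO.

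Each array had 45018 spots, 43379 of them non-control. Spots with a non-uniformity or population outlier flag were left out (115 on WT, 103 on KO), and no spot was saturated. The log2 signal minus the array's 75th percentile over the remaining non-control spots was the main value, and the spots of a probe were averaged. The probes comprised 40929 printed once and 245 printed 10 times. Scanner files give accessions and no gene names, so names came from a RefSeq gene table of GRCm38.p6, which was used for names and for the order of neighbouring genes only. Of 41174 probes 27050 had 1 symbol, none had several and 14124 had none, and the named probes covered 18434 symbols.

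A gene with several probes took the probe with the highest mean level among those well above background on at least 1 array. Of 4414 genes with several probes measured on both arrays, 524 had a probe at least 2-fold apart, and 35 of these had probes of opposite sign. Where 1 array was not well above background, the difference is a bound. It is the bright value minus the higher of the dim probe's own value and the lowest level well above background on that array. For 276 genes no usable bound was left. Such genes enter list medians at their bound.

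The design fixed before the data were examined was 1 array against 1, with no test. The size rule was a log2 difference of 1 or more, and a gene list was described by its median and that median's percentile among 10000 random lists of the same size, drawn to match its members over 20 bins of mean level. These percentiles describe the 2 arrays and are not p-values. A list of under 5 measured genes got no percentile. The 34 gene lists were fixed before the data were examined, as was the rule for named genes: Men1 and Bach2; the 10 largest differences in each direction measured on both arrays with probes of the same sign; the 5 largest bounds in each direction; the 4 members of each list with the largest difference; any member of the lists on cytokines, Th1 and Th2 genes, senescence, naive genes, AP-1 and Menin; the 2 brightest markers of each other cell type; and Xist with 3 Y-linked genes. Predicted genes and clone names were left out of the ranked parts, and some genes that meet the rule are not reported here.

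Alternatives comprised normexp background correction (offset 50), quantile normalization, median centring, loess on level, the authors' values, the mean over a gene's probes, 3 filters on dim probes, kept outlier flags, size rules of 1.5-fold and 4-fold, and lists without members they share. Normexp had been planned on mean spot signals, but the median spot signals and local median backgrounds were used, since the files as used here hold no mean signal column. The WT array held 6 spots with a local background over 200 and the KO array none. The fitted residual background was -140.5 on WT as given, -12.9 with those 6 replaced by the array's median background, and -1.60 on KO. That replacement, and a common detection limit for both arrays, were added after the data were seen.

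The technical spread came from probes with at least 5 usable spots, as a pooled SD over the spots of a probe. On each array alone it was 0.110 (WT) and 0.108 (KO) on the log2 scale. The 8 spike-in probes had a median log2 difference of 0.09 (range 0.02 to 0.22). The number of arrays limits the precision.

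The procedure was tested on simulated data, made from the WT array with spot noise of the measured size and 200 genes shifted by known amounts. All 67 genes shifted 4-fold and all 66 shifted 8-fold were at least 2-fold apart, as were 2 of 67 shifted 1.5-fold and 0 of 12506 unshifted genes. This simulation holds spot noise only. In 40 random lists of 20 genes the mean percentile was 60.9, higher than the 50 of an unbiased procedure, so 200 further lists were drawn, which had a mean of 52.7, with 9 beyond the 2.5th or 97.5th percentile. A list shifted by 1 log2 unit came out at percentile 100. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, R 4.3.3 with limma 3.58.1 for normexp, and matplotlib 3.10.9 were used.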

Results

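Gene expression was measured in mouse CD4 T cells with and without Menin, the protein encoded by Men1 and a partner of MLL histone methyltransferases in transcription complexes. The series title sets a Menin-Bach2 axis against T cell senescence and cytokine balance, so the comparison asked which genes differed when Menin was missing. There was 1 array of Menin WT cells and 1 array of Menin KO cells. Naive splenic CD4 T cells of female C57BL/6J mice were stimulated through the T cell receptor and CD28 for 2 days with IL-2 and then kept in IL-2 for 3 more days. The arrays carried 41174 different probes, of which 41164 had a value on both. Of the non-control spots, 59.5% were well above background on the WT array and 63.5% on the KO array, and the 75th percentile of signal was 644 and 650. A total of 13786 named genes were well above background on at least 1 array, 12475 of them on both.

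With no replicate arrays, no difference was tested and none has a p-value. All values are KO against WT on these 2 arrays, as a fold or as a log2 difference. For probes spotted several times on each array, the difference between the arrays varied from spot to spot with a pooled SD of 0.142 on the log2 scale (146 probes). The SD was 0.271 for signals under 100 and 0.0536 for brighter ones. This technical spread is scatter around each probe's own difference. It leaves out differences between mice, cultures, RNA preparations, labelling reactions and hybridisations. Where a gene was well above background on 1 array only, its difference is a bound and is written as at least N-fold. A bound under 2-fold leaves open on which side of the 2-fold limit the gene lies, so such genes are counted apart.

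Men1 itself was lower in the KO array, with a signal of 1081 in WT and 459 in KO, a 2.38-fold difference (log2 difference -1.25). It was read by 1 probe, and whether that probe lies inside the deleted part of the gene is not known here, so the remaining signal gives no measure of how complete the deletion was. Bach2, a transcriptional repressor of effector genes in lymphocytes, was 7.76-fold lower in KO, with a signal of 4643 in WT and 604 in KO. Both differences were many times the technical SD, which holds spot scatter only. The other measured genes of the Menin and MLL complexes were less than 2-fold apart. Kmt2a, encoding MLL1, had no named probe, so Kmt2d was the only MLL methyltransferase gene of the list that was read. Of the 10 measured, 1 (Men1) was at least 2-fold lower, none was at least 2-fold higher and 9 lay between, among them Kmt2d (log2 difference -0.12), Ash2l (-0.12) and Psip1 (-0.69). The list median was -0.15, at the 18th percentile of 10000 random lists of the same size matched on level.

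Across all genes, more were higher than lower in the KO array. At least 2-fold differences were found for 1458 genes higher in KO and 694 lower, while 10807 genes measured on both arrays lay between and 551 had a bound under 2-fold. With no filter on dim probes the counts were 2121 and 1113. Differences of at least 4-fold were found for 542 higher and 158 lower genes, and of at least 16-fold for 72 and 15. Among genes measured on both arrays, those most strongly higher in KO were Krt19, a keratin (95.9-fold), Vat1l (61.9-fold), Igsf5 (48.8-fold), Col18a1, the collagen XVIII chain (45.5-fold), and Il1r2, the decoy receptor for interleukin 1 (37.5-fold). Gstm5 (35.3-fold), Tmem119 (35.2-fold), Spns2, a sphingosine-1-phosphate transporter (34.4-fold), Anxa1, annexin A1 (33.7-fold), and Scin, an actin-severing protein (30.8-fold), came next. The WT signal under these folds was dim for Vat1l (16.1), Krt19 (20.4), Spns2 (22), Igsf5 (23.3), Tmem119 (25.1), Gstm5 (28) and Scin (67.3). It was brighter for Col18a1 (119), Il1r2 (156) and Anxa1 (206). Folds on dim signals, and their order, depend on the background subtraction. Among the same genes, those most strongly lower in KO were Gpr83, a G protein-coupled receptor (187-fold), Dapl1 (126-fold), Pdlim4 (40.2-fold), Fbln2, an extracellular matrix fibulin (37.2-fold), and Nsg2 (30.3-fold). They were followed by the interferon-stimulated gene Ifit3 (24.3-fold), Tcf7, encoding the transcription factor TCF-1 (22.2-fold), Nt5e, encoding the ecto-nucleotidase CD73 (17.3-fold), the DNA primase subunit Prim2 (16.4-fold) and Nfatc2 (16.1-fold, although another of its 3 probes gave a log2 difference of only -0.21). The same limit holds where the KO signal was dim: Dapl1 (16.8), Fbln2 (28.2), Nfatc2 (29.9), Gpr83 (32.2), Ifit3 (37.9), Nt5e (60.4) and Pdlim4 (62). Tcf7 (110), Nsg2 (175) and Prim2 (264) were brighter in KO. Genes whose chosen probe was well above background in KO only included Pde6b (at least 46.3-fold higher), Ttc23l (40.9-fold), Gulo (39.4-fold, although its other probe, read on both arrays, gave a log2 difference of 0.50), the PDGF receptor gene Pdgfrb (35.7-fold) and Il5 (34.0-fold). In WT only they included Evx1 (at least 30.2-fold lower in KO), Sema3b (27.7-fold), Imp4 (19.3-fold), Cym (18.6-fold) and Sel1l3 (16.2-fold). The share of higher genes among those at least 2-fold apart was 67.8%. It was 26.3% (601 higher, 1682 lower) after the normexp background correction, whose WT fit was set by 6 spots with aberrant local background. With those backgrounds replaced it was 67.3% (760 higher, 369 lower).

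**Figure D1:**
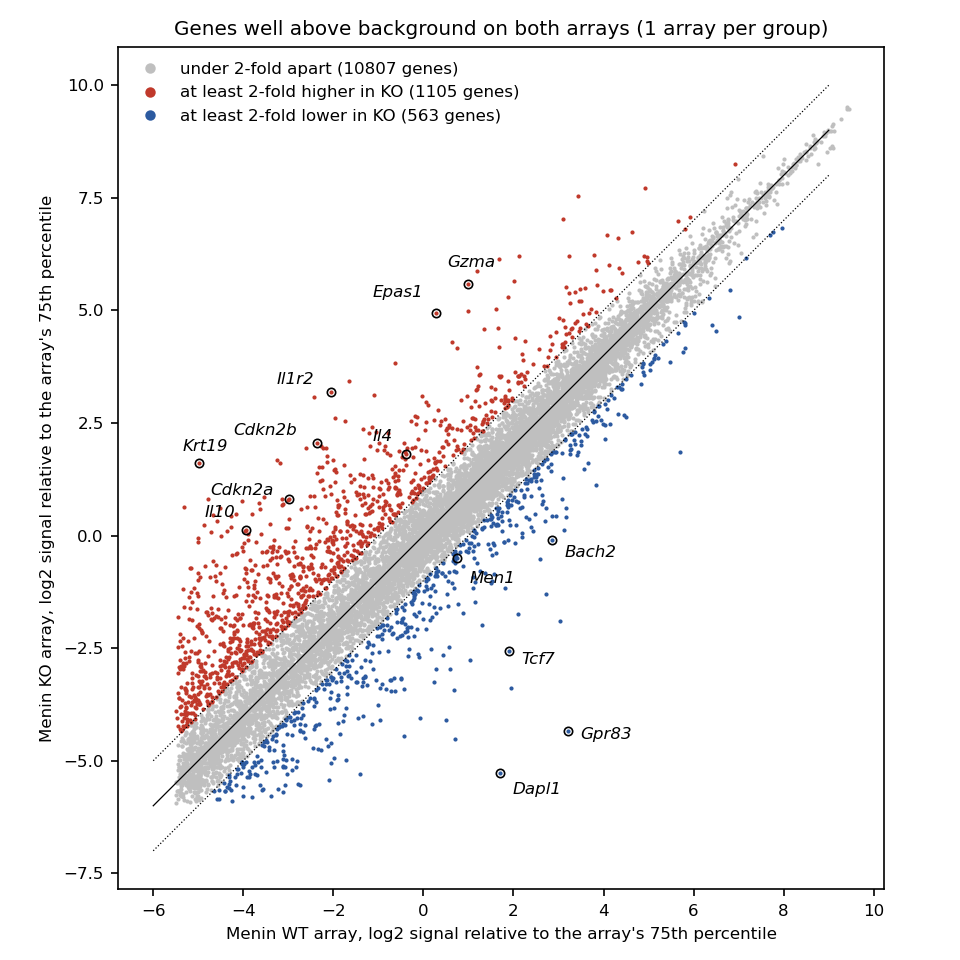
Each point is a gene well above background on both arrays, with its log2 signal relative to the array's 75th percentile in Menin WT (x axis) and Menin KO (y axis). The solid line marks equal signal and the dotted lines 2-fold; 1105 genes lie above the upper dotted line and 563 below the lower one, with Men1, Bach2 and selected genes named in the text circled.

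Th2 cytokines were higher in the KO array as a group. Of 8 measured, 6 were at least 2-fold higher, none was at least 2-fold lower and the other 2 had bounds under 2-fold. Il10, an anti-inflammatory cytokine, was 16.8-fold higher, Il4, the signature Th2 cytokine, 4.60-fold, Csf2, encoding GM-CSF, 4.11-fold, and Il5, which drives eosinophil growth, at least 34.0-fold. The list median was 1.85, above all 10000 random lists, and 3 of its members were bounds. Th2 regulators and receptors had a median of 1.01, also above all random lists, with 8 of 15 at least 2-fold higher and 7 between. The hypoxia-responsive factor Epas1 was 25.5-fold higher, the transcription factor Maf 13.6-fold, the nuclear receptor Pparg 11.2-fold and Prdm1, encoding Blimp-1, 6.88-fold. Gata3, the master regulator of Th2 cells, was 1.80-fold higher and so below the 2-fold limit, while Stat6 had a log2 difference of -0.06. The markers of mast cells and basophils Cpa3 (12.9-fold), Mcpt8 (at least 11.4-fold) and Fcer1a (2.33-fold, but a log2 difference of -0.51 after normexp), cells that also make Th2 cytokines, were higher in the same array. Other markers of these cells did not follow: Prss34 had a log2 difference of 0.24 and Gata2 a bound of 0.35. Ms4a2 was not well above background on either array.

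Genes of the other helper cell types went both ways. Among Th1 genes 5 of 16 were at least 2-fold higher in KO, 6 lower and 5 between, with a median of 0.37 at percentile 99.8 (0.56 without members shared with other lists). The chemokine receptor Cxcr6 (23.7-fold) and the homeobox factor Hlx (17.9-fold) were higher, whereas the cytokine genes Lta (3.25-fold) and Tnf (2.85-fold) and the chemokine receptor Cxcr3 (3.04-fold) were lower. Ifng, the signature Th1 cytokine, was 1.64-fold higher and its regulator Tbx21 had a log2 difference of 0.19. Of 7 Th17 genes 3 were higher, 1 lower and 2 between, and 1 had a bound under 2-fold. Their median of 0.91 (percentile 98.2) became -0.08 after normexp, 0.52 with the aberrant backgrounds replaced, 0.51 with no filter on dim probes and 0.36 as the mean over probes. The aryl hydrocarbon receptor Ahr was 4.81-fold higher, Il1r1 at least 3.48-fold and Batf 2.54-fold, while Il17f was 2.41-fold lower. Regulatory T cell genes had a median of 0.00 at percentile 49.6 (-0.15 after normexp), with 2 of 13 higher, 4 lower and 7 between. The lower ones were Gpr83 (187-fold), the folate receptor family gene Izumo1r (8.56-fold), Ikzf2 (log2 difference -1.93) and the lineage factor Foxp3. Foxp3 was not well above background in KO and had a bound of -1.51. The ecto-nucleotidase Entpd1 (8.14-fold) and the integrin Itgae (7.81-fold) were higher. Of 9 follicular helper genes, 1 was higher (Pdcd1, 2.40-fold), 3 were lower and 5 lay between, with a median of -0.42 at percentile 1.35 (-0.78 after normexp, -0.14 with no filter on dim probes). The lower ones were Btla (6.48-fold), Bcl6, the lineage factor of these cells (3.29-fold), and Cd200 (2.72-fold).

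Secreted factors associated with senescence went both ways. Of 29 measured, 9 were at least 2-fold higher in KO, 5 lower and 10 between, while 5 had bounds under 2-fold, all on the higher side. The largest values were those of Il1a (at least 31.9-fold higher), Il10 (16.8-fold), Spp1, encoding osteopontin (8.78-fold), Ccl9 (log2 difference 2.81), Csf1 (6.41-fold) and Ccl5 (4.84-fold). Timp2, an inhibitor of matrix metalloproteinases, was 7.84-fold lower, and Igfbp7 (3.33-fold), Tnf (2.85-fold), Cxcl10 (2.18-fold) and Igfbp4 (2.01-fold) were lower as well. The list median was 0.35 (percentile 99.5), but over the 23 members well above background on both arrays it was -0.11, and it was 0.59 after loess and 0.043 with aberrant backgrounds replaced. In the same KO array 3 of 8 macrophage and monocyte markers were at least 2-fold higher: Cd14 (7.25-fold), Fcgr3 (at least 9.50-fold) and Adgre1 (at least 5.08-fold). Other such markers did not follow: the log2 difference was -0.64 for Mpeg1, -0.39 for Csf1r and 0.002 for C1qb. Lyz2 was not well above background in KO.

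Among senescence regulators, 3 of the 4 Ink4 family cell cycle inhibitors were at least 2-fold apart. Cdkn2b, encoding p15, was 21.3-fold higher in KO and Cdkn2a, encoding p16 and p19ARF, 13.8-fold higher, whereas Cdkn2c, encoding p18, was 3.22-fold lower and Cdkn2d, encoding p19, had a log2 difference of -0.17. The other 17 of 20 members of this list lay between, among them Cdkn1a, encoding p21 (1.69-fold higher), Cdkn1b, encoding p27 (1.77-fold lower), Trp53 (log2 difference -0.19), Lmnb1, whose loss marks senescent cells (1.60-fold lower), and Glb1, encoding the beta-galactosidase used as a senescence stain (1.80-fold higher). The list median was -0.23 at percentile 2.66. Since the list mixes cell cycle inhibitors with genes whose loss marks senescence, such as Lmnb1, this median speaks neither for nor against senescence. Targets of p53 had a median of 0.06 at percentile 80.1 (0.23 after normexp), with 1 of 18 at least 2-fold higher (the proapoptotic gene Pmaip1, 2.46-fold) and 17 between. Apoptosis regulators had a median of -0.07 (percentile 34.5; 0.002 after loess), with 3 of 20 higher, 1 lower and 16 between: the higher ones included Casp1 (3.57-fold) and Bmf (3.07-fold, although the other of its 2 probes gave a log2 difference of 0.02), and the death receptor Fas was 3.99-fold lower.

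**Figure D2:**
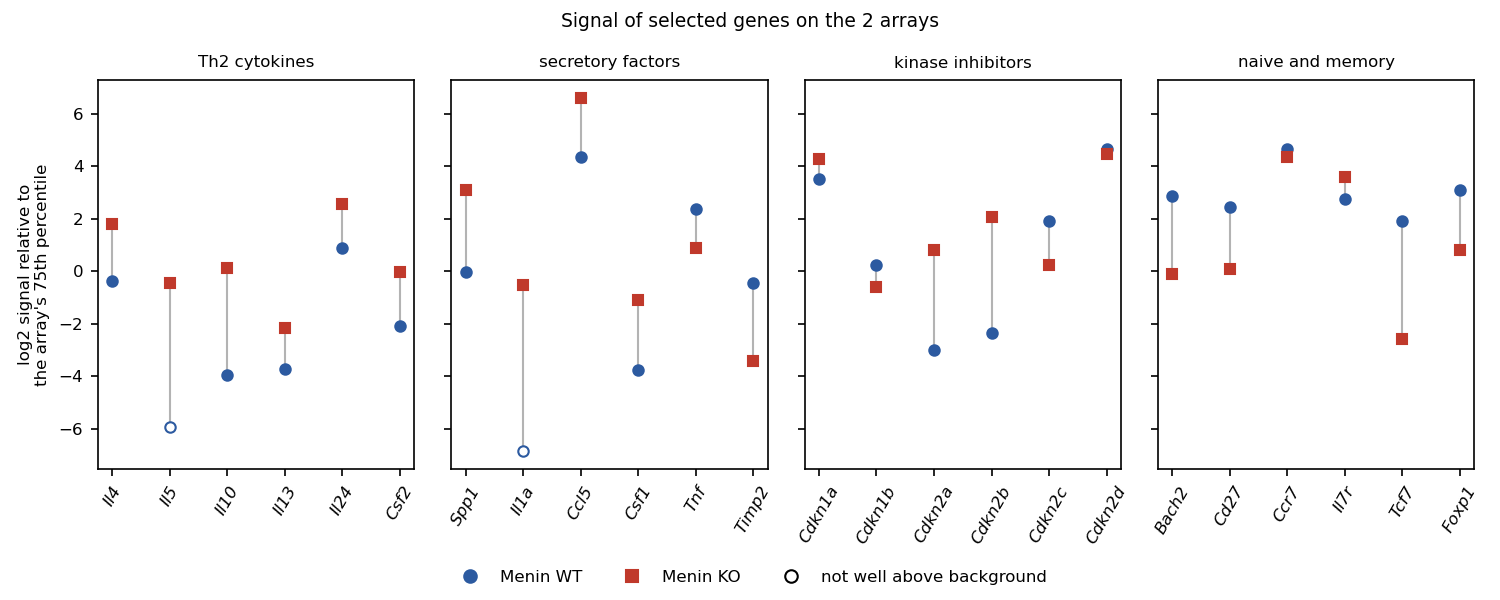
Log2 signal relative to the array's 75th percentile (y axis) of 24 genes in 4 groups (x axis) on the Menin WT array (circles) and the Menin KO array (squares), with open symbols where the signal was not well above background. Cdkn2a and Cdkn2b lie 3.78 and 4.41 log2 units higher in KO, and Tcf7 lies 4.47 lower.

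Genes of naive and memory T cells were lower in the KO array. Of 23 measured, none was at least 2-fold higher, 14 were at least 2-fold lower and 9 lay between, and the median of -1.36 was below all 10000 random lists. Besides Dapl1, Nsg2, Tcf7 and Bach2, the costimulatory receptor Cd27 was 5.02-fold lower and the quiescence factor Foxp1 4.84-fold. The homing receptor Ccr7 was 1.22-fold lower, and Il7r, the receptor for the survival cytokine IL-7, was 1.78-fold higher. Genes of the T cell receptor and of activation also had a median below all random lists, -0.61 (-0.38 after normexp), with 5 of 25 lower, 19 between and 1 bound under 2-fold. They included Cd6 (3.84-fold lower) and Cd5 (3.32-fold lower), both restraining receptors of T cells, the adhesion receptor Cd2 (2.32-fold lower) and the transferrin receptor Tfrc (2.26-fold lower).

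Cytotoxic effector genes were higher in the KO array, with 14 of 19 at least 2-fold higher, none lower and 5 between. The granzyme genes Gzmg (27.8-fold), Gzma (24.2-fold) and Gzme (17.9-fold) and the perforin gene Prf1 (26.0-fold) had the largest differences. The list median of 2.43 was above all random lists, and was 1.22 after normexp and 1.67 with the aberrant backgrounds replaced. Granzymes C to G are near-identical copies, so a probe of one may also read another. The CD8 T cell marker Cd8a, the only 1 of 2 listed with a probe, was 10.2-fold higher in the same array. Among markers of natural killer cells Fcer1g was 7.54-fold higher, Klrb1c 5.40-fold and Tyrobp 4.83-fold. Of 11 natural killer and innate T cell markers 5 were at least 2-fold higher, 5 between and 1 had a bound under 2-fold. Their median was 0.99 (percentile 99.95), or 0.59 after normexp and 0.52 with backgrounds replaced. Among inhibitory receptors 6 of 15 were higher, 2 lower and 7 between, with a median of 0.79 at percentile 99.98. That median was 0.04 after normexp and 0.35 with the aberrant backgrounds replaced. Havcr2, encoding TIM-3 (19.4-fold), Cd244a (8.46-fold) and Cd200r1 (7.72-fold) were higher, and Tox, a regulator of T cell exhaustion, was at least 12.7-fold lower. Integrin, homing and chemokine receptor genes had a median of 0.47 (percentile 99.7), with 4 of 15 higher, 10 between and 1 bound under 2-fold, led by Ccr2 (21.2-fold), Itgae (7.81-fold) and Cxcr4 (3.64-fold).

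Transcription factors of the AP-1 and Bach families compete for related DNA sites. Of 19 measured, 9 were at least 2-fold higher in KO, 2 lower (Bach2 and Nfe2l2) and 8 between, with a median of 0.56 at percentile 99.94 (0.85 over genes brighter than the median probe). Maf (13.6-fold), Fosl2 (6.10-fold) and Batf (2.54-fold) were higher, Junb was 2.22-fold and Jun 2.39-fold higher, and Nfe2l2, the factor of the oxidative stress response, was 3.72-fold lower. Hoxa cluster and Meis genes, which depend on Menin and MLL in leukaemia cells, had 7 members well above background. Of these 4 were at least 2-fold higher, none lower and 3 between, with a median of 1.03 at percentile 95.3 that became -0.13 after normexp, 0.39 with the aberrant backgrounds replaced and 0.17 with no filter on dim probes. Meis2 (at least 3.22-fold) and Meis3 (2.04-fold) were higher.

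Most cell division genes were lower in the KO array, mitosis genes by more than DNA replication genes. All 25 mitosis genes were below 0, 15 of them at least 2-fold lower and 10 between, with a median of -1.05. The kinesin Kif11 was 2.80-fold lower, Ccna2, cyclin A2, 2.75-fold, the centromere protein gene Cenpf 2.70-fold and Top2a, the topoisomerase of dividing cells, 2.66-fold. DNA replication genes had a median of -0.73 with all 26 between the 2-fold limits, such as Pola1 (1.98-fold lower) and Tyms (1.86-fold lower). Both medians were below all random lists. Interferon-stimulated genes had a median of -0.76, also below all random lists, with 1 of 25 higher, 8 lower and 16 between. Ifit3 was 24.3-fold lower, Usp18, which restrains interferon signalling, 6.81-fold, Ifit2 5.36-fold and Rtp4 3.68-fold.

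Genes of metabolism and protein synthesis were nearly equal on the arrays. None of 20 glycolysis genes, 25 oxidative phosphorylation genes, 24 cholesterol synthesis genes and 28 ribosomal protein genes was 2-fold apart. Their medians were 0.09 (percentile 87.3), 0.10 (percentile 92.1), 0.06 (percentile 84.2) and -0.004 (percentile 30.2), the last of them above 0 after several of the other scalings. After normexp they were 0.36, 0.39, 0.24 and 0.26. The glycolysis gene Pgam1 was 1.43-fold higher and the kinase gene Pdk1 lower (log2 difference -0.58). Genes of the unfolded protein and amino acid stress responses had a median of 0.42, above all random lists, with 2 of 23 at least 2-fold higher, 20 between and 1 bound under 2-fold. These 2 were the stress factor Atf3 (2.27-fold) and the asparagine synthetase gene Asns (2.07-fold), next to Chac1 (1.96-fold) and Sdf2l1 (1.94-fold).

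Markers of other cell types were measured because the cultures could hold other cells. B cell and plasma cell markers had a median of 1.01 (percentile 99.3), which became -0.29 after normexp and 0.56 with the aberrant backgrounds replaced, with 5 of 9 at least 2-fold higher in KO, 3 between and 1 bound under 2-fold. Cd74, the invariant chain of MHC class II, was 2.36-fold higher, while Cd79b was 1.72-fold higher. Dendritic cell markers had a median of 0.78 (percentile 97.3; 0.04 after normexp, 0.39 with backgrounds replaced and 0.38 with no filter on dim probes), with 4 of 8 higher and 4 between: the integrin Itgax, CD11c, was 30.8-fold higher and the class II gene H2-Ab1 2.49-fold. Macrophage and monocyte markers had a median of 0.29 (percentile 79.2), which became -0.70 after normexp, -0.03 with no filter, 0.58 over genes brighter than the median probe and 0.002 over members well above background on both arrays. Of 8 measured, 3 were higher and 4 between, and Lyz2, not well above background in KO, had a bound under 2-fold on the lower side. Granulocyte and mast cell markers had a median of 0.35 (percentile 76.9), with 3 of 7 higher, 3 between and 1 bound under 2-fold. It became -0.78 after normexp, -0.39 with no filter, 0.18 with backgrounds replaced, 0.23 by quantile normalization and 2.37 over genes brighter than the median probe. Of 4 erythroid and platelet markers 1 was higher (Hba-a1, 2.74-fold) and 3 lay between. Stromal and endothelial markers had a median of 0.13 (percentile 65.4; -0.39 after normexp, -0.007 with backgrounds replaced and 0.45 over genes brighter than the median probe). Of 9 measured, 1 was higher (Pdgfrb), 1 lower (Kdr, at least 2.60-fold) and 5 between, with 2 bounds under 2-fold. For the female mice named in the labels, Xist was present on both arrays at a signal of 12052 in WT and 7427 in KO, and the Y-linked genes Ddx3y and Kdm5d were not well above background on either. A further Y-linked gene, Eif2s3y, was above background in KO only, at a signal of 35.4.

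**Figure D3:**
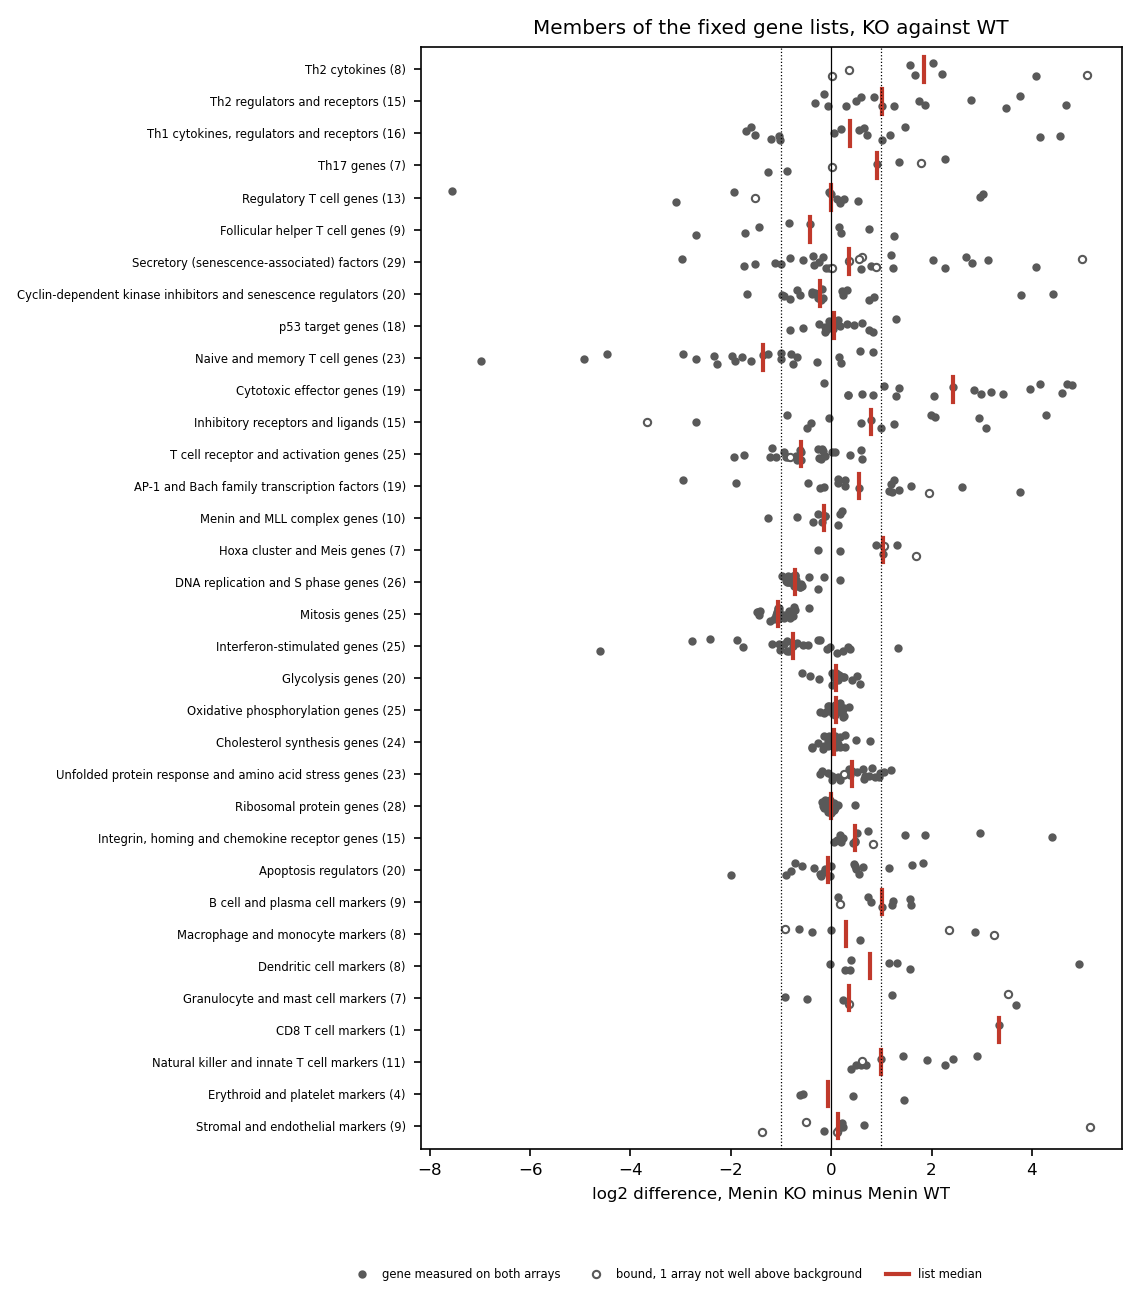
Log2 difference, Menin KO minus Menin WT (x axis), of each measured member (points, open for bounds) of the 34 gene lists (y axis, number measured in brackets), with the list median as a red bar and dotted lines at 2-fold. Naive and memory genes centre on -1.36, mitosis genes on -1.05, Th2 cytokines on 1.85 and cytotoxic effector genes on 2.43, while ribosomal protein genes lie close to 0.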

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

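The tests of brighter genes for the WT background and of the signal level of cDNA clone probes were chosen after the results they bear on were seen. The former took the place of a test on a common detection limit, which equals that of the WT array and so removes lower genes only. Single macrophage genes were also picked afterwards, and the bootstrap intervals over genes were added then.

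Probes without a gene symbol lie outside the gene comparison, and 391 of the 6624 well above background were at least 2-fold higher in KO, while 632 were at least 2-fold lower. Most of the lower ones belonged to cDNA clones with accessions of the AK type, with 343 of 2642 lower, 138 higher and a median log2 difference of -0.371 (-0.214 after loess, -0.998 after normexp and -0.295 with aberrant backgrounds replaced), against -0.02 for named probes. The clone probes behind these medians changed with the setting: 2542 in the main one, 2611 after loess, 2342 after normexp and 2455 with backgrounds replaced. Dim signal as the cause is argued against by 1000 sets of named probes matched on level, whose medians were -0.03 or higher. Less nuclear RNA in the KO sample would have needed a median of nuclear noncoding RNAs at or below -0.185. The median was 0.46 over the 10 RNAs taken as nuclear (bootstrap 95% interval -0.001 to 1.129), 2 of which were lower. With Xist (log2 difference -0.71, 4 of 4 probes lower), which the test left out, it was 0.404. These RNAs, among them Norad, Snhg3 and Rmrp, are not all confined to the nucleus, and Meg3 (2.78) and Rian (1.60) entered as bounds. The set therefore cannot settle whether nuclear RNA was lower. A lower level of the clone transcripts without Menin may be the reason and remains a hypothesis, since what the clones encode was not analysed here and sample differences other than genotype stay open.

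The number of genes at least 2-fold apart, 1458 higher and 694 lower in KO, could arise from a bias between the arrays. Removing the trend on signal by loess left 93.03% of them apart in the same direction, which argues against such a trend as the whole cause. The loss was on 1 side: all 1458 higher genes stayed apart but only 544 of the 694 lower ones. The share of higher genes was 75.27% after loess against 67.75% before. The noisier WT background (SD of negative controls 2.81 against 1.99) could be a source of the excess of higher genes. Among genes whose mean level was above the median of all probes, 67.39% of those apart were higher. The Wilson 95% interval, which takes genes as independent, was 64.99% to 69.69%, above the 58.88% set as the limit. That mean over both arrays also lets in genes at background in WT, such as Il5 (signal 10.6 in WT, 480.6 in KO). Over genes well above background on both arrays the share was 66.25% (1105 higher, 563 lower). The excess was therefore not confined to genes lost in the WT background, but a part of that background in it is not excluded. For strain variants carried along with the Men1 allele, the limit was a share over 31.25% apart among the 100 nearest genes above background on at least 1 array. There 13% were apart (Wilson 95% interval 7.76% to 20.98%), against 15.6% of the other 13685. This argues against a broad effect of such variants near Men1 itself. It cannot exclude variants that alter a few of the neighbours. Loss of Menin may account for the differences, but with 1 array per group differences between mice, cultures or RNA preparations were not tested and stay open.

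The higher cytotoxic genes could come from CD8 T or natural killer cells in the KO culture. The 12 markers were 11 natural killer and innate T cell genes and, for CD8 T cells, Cd8a alone, so their median bears little on CD8 T cells. It was 1.209 where 1.217, 50% of the cytotoxic median, was the limit. The bootstrap 95% interval of the gap over the members of both lists, -0.905 to 1.438, leaves either side possible, so this source and a difference within CD4 T cells cannot be told apart; Cd8a was 10.2-fold higher, although isolation by CD4 should remove CD8 T cells. For the secretory factors, macrophages were weighed as a source, and their marker median of 0.29 was set against a limit of 0.177, with an interval of the gap from -0.814 to 2.655, so this source and T cells cannot be told apart. Single markers went both ways: Cd14 was 7.25-fold, Fcgr3 at least 9.50-fold and Adgre1 at least 5.08-fold higher, and Ly6c1 had a log2 difference of 0.58. Mpeg1 (log2 difference -0.64), Csf1r (-0.39) and C1qb (0.002) were not higher, and Lyz2 was not well above background in KO. Activated T cells may themselves express several of these markers, which was not tested.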

How the results depend on the processing

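The normexp setting with aberrant backgrounds replaced and the common detection limit were chosen after seeing the data. No paired analysis was possible because each group has 1 array and no result comes from a test. Over the counts, Men1, Bach2 and the 8 core lists, 125 of 156 values under an alternative lay near the main one. Near meant within 0.142 for a log2 value and within a factor of 1.5 for a count. Some alternatives could hardly move a value, so this tally is no measure of robustness. The authors' values and median centring shift the main values by a near constant. For Men1 and Bach2, each read by 1 probe, the filters and the mean over probes return the main value.

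The counts, 1458 higher and 694 lower, became 2338 and 1712 at 1.5-fold, 542 and 158 at 4-fold, 601 and 1682 under normexp and 760 and 369 under normexp with aberrant backgrounds replaced. With no filter on dim probes they were 2121 and 1113. The residual background fitted on the WT array, -140.5 as given and -12.9 with 6 spots replaced, accounts for the turned split. Men1 was -1.02 and Bach2 -2.57 under normexp, and -1.10 and -2.77 with backgrounds replaced.

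The Th2 cytokine median was 2.12 without dim genes or with no filter, 2.04 measured on both arrays and also by quantile normalization (2.036), 1.67 without shared members and 1.69 under normexp. Th2 regulators were 0.75 under normexp and 0.86 with backgrounds replaced, Th1 genes 0.55 under normexp and 0.56 without shared members, naive and memory genes -0.95 with backgrounds replaced, and AP-1 factors 0.85 without dim genes. The secretory median was 0.59 after loess, 0.56 without shared members and 0.043 with backgrounds replaced. It turned to -0.043 without dim genes, -0.007 with no filter and -0.11 measured on both arrays. In the last of these the bounds, which all lie above 0, drop out, and for the others the cause was not tested.

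Under normexp the B cell (-0.29), Th17 (-0.078), Hoxa and Meis (-0.13), macrophage (-0.70), granulocyte (-0.78), stromal (-0.39) and regulatory T cell (-0.148) medians and Fcer1a (-0.51) turned. The same WT fit is the likely cause, except for the stromal and regulatory medians, which also lay below 0 with backgrounds replaced (-0.007 and -0.035). With no filter the macrophage (-0.03) and granulocyte (-0.39) medians turned too, and the apoptosis, ribosomal and regulatory medians, close to 0, took either sign. The median of the 4 erythroid and platelet markers, -0.058, was -1.113 under normexp, 0.435 with no filter, 0.119 after loess and 1.454 without dim genes. Of 126 genes in the text at least 2-fold apart, Foxp3 and Ikzf2 not counted, 18 were under 2-fold after normexp and 14 with backgrounds replaced. The glycolysis (0.36), oxidative phosphorylation (0.39), cholesterol (0.24) and p53 target (0.23) medians lay further above 0 after normexp, and the ribosomal protein median turned from -0.004 to 0.26. Signal over background sets what can be read: the technical SD was 0.271 under a signal of 100 and 0.0536 above.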

Other observations

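The gene families described here were chosen after their values were seen, among 220 families of at least 8 measured genes that share a symbol stem. Of these, 10 lay above the 99.5th and 11 below the 0.5th percentile of random lists matched on level, where 2.2 in all would be met by chance if genes were independent. Genes of a family can vary together or share signal, so the excess is not a measure of biology. The 11 include the large families Olfr (208 genes, median -0.08) and Zfp (291 genes, median -0.20), for which a small median was enough. Genes of the Ms4a family of membrane proteins were lower in KO under every scaling tried, with 7 of 10 at least 2-fold lower, 2 higher and a median of -2.01. Ms4a4d (8.32-fold), Ms4a4c (8.04-fold) and Ms4a4b (4.46-fold) were lower, while Ms4a3 (at least 6.07-fold) and the B cell gene Ms4a1 (2.01-fold) were higher. Interferon-inducible Ifi genes (median -0.57; 4 of 11 lower, among them Ifi204 at 4.40-fold), the chromatin genes of the Arid family (-0.59; 1 of 9 lower), nucleoporins (-0.38; 0 of 20 apart) and Cep genes, most of them centrosomal, (-0.33; 2 of 35 lower, 1 higher) were also lower on balance under every scaling.

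On the other side, annexins, which bind membranes in a calcium-dependent way, had a median of 0.66, with 3 of 10 at least 2-fold higher: Anxa1 (33.7-fold), Anxa3 (6.51-fold) and Anxa4 (3.18-fold). Genes with the stem Casp, all caspases except Casp8ap2, had a median of 0.48, with 4 of 10 higher, led by the inflammatory caspase Casp1 (3.57-fold), and chemokine receptors of the Ccr family had 0.84 (0.281 under normexp and 0.148 with backgrounds replaced), with 4 of 9 higher and 1 lower. All 3 medians stayed above 0 under every scaling. Tetraspanins had a median of 0.93, with 6 of 15 higher and 1 lower, and kallikreins one of 1.32, with 9 of 16 higher, but under normexp these medians turned to -0.04 and -0.20. The kallikrein median was 0.41 with backgrounds replaced and 0.857 measured on both arrays. The kallikrein genes are close copies and were dim, so a probe may read more than 1 of them.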
